A study of Mus musculus with 19 samples.

How the data were processed

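T cell receptor beta (TRB) transcripts were measured in 19 libraries of sorted CD4+ T cells from BALB/c mice. Each library was made from the total RNA of 500000 sorted cells for lymph nodes, or of 5000 sorted cells for hearts, taken 7 days after surgery or immunization. Per the labels, the provider amplified TRB transcripts by amplicon-rescued multiplex PCR with V-segment primers, pooled equal masses of all 19 libraries and sequenced the pool on an Illumina HiSeq. The deposited tables list, per the labels one library each, a read count for every combination of a CDR3 amino acid sequence, a TRBV segment and a TRBJ segment. The values are unnormalised read counts in whole numbers, and the lowest count listed in any library was 2, so an unlisted CDR3 had at most a single read or was removed upstream. The aligner, the error correction and the reference behind the segment names are not given in the sources used here, and no molecular identifiers are mentioned. The PCR reads are therefore not independent molecules, and every confidence interval and detection floor below covers counting error only. CDR3 strings are printed as the tables give them, without the leading cysteine and the closing phenylalanine. The tables name no genome build, so no coordinates are given.

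Read totals ran from 7534295 to 9235800 in the 16 lymph node libraries and from 2426715 to 5126910 in the 3 heart libraries. Reads were summed per TRBV segment, per TRBJ segment and per CDR3 amino acid sequence. Samples were grouped by tissue and treatment as labelled: mediastinal nodes after sham surgery (n = 4) or myocardial infarction (MI, n = 3), infarcted hearts (n = 3), and axillary nodes after adjuvant alone (n = 4), 100 µg of porcine cardiac myosin (n = 2) or 1 mg of heart extract (n = 3). The labels do not say whether each library came from 1 animal, so p-values measure the spread between these samples. They also give the adjuvant volume for immunised animals as either of 2 values without assigning them to samples, and name the lower value for the adjuvant control, so volume and antigen cannot be separated here.

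Segment and CDR3 counts were compared with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (glmQLFit with robust estimation and legacy settings, glmQLFTest), with the library total as offset and Benjamini-Hochberg adjustment at 0.05 within each comparison. All 16 lymph node libraries in 5 groups shared a fit, and the heart was compared with the MI node in a separate fit of 6 libraries, because hearts held far fewer sorted cells. CDR3s entered a fit with a read in at least 3 libraries and at least 20 reads in all. For the contrast of both antigens with adjuvant, the antigen groups were averaged in proportion to their libraries. The named-gene rule was fixed before the data were examined. It took every segment with an adjusted p under 0.05, up to 12 by smallest p, and otherwise the 4 segments with the smallest p, given as not passing. For CDR3s it took the 10 with the largest positive and the 5 with the largest negative log2 fold change among those past the threshold, or, if fewer than 5 passed, the 5 with the smallest p. The most abundant CDR3 of a library could also be named. The rule's last part, CDR3s in all 3 heart libraries, found 0. Fold changes against a group without reads are lower bounds against a floor of 3 reads in each library of that group, averaged as shares.

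Diversity, CDR3 features and segment lists were computed per library after drawing reads without replacement to the smallest total among the libraries compared, and were tested by exact two-sided permutation of the group labels with Benjamini-Hochberg adjustment within each family and comparison. The measures were distinct CDR3s, normalised Shannon entropy and the share of reads in the 100 most abundant CDR3s. The features were mean CDR3 length, the share of CDR3s with a hydrophobic residue pair at CDR3 positions 6 and 7 and the mean net charge of the CDR3 centre. The lists were the TRBJ1 cluster, the TRBV13 family, TRBV19 and the 5 segments that mouse mammary tumor virus superantigens delete in BALB/c mice (TRBV26, TRBV12-1, TRBV12-2, TRBV16 and TRBV15). No markers of other cell types could be listed, because only TRB transcripts were amplified. Overlap between libraries was the Morisita-Horn index of CDR3 read shares at 2426715 drawn reads, tested by exact permutation. Sharing was the percentage of a heart library's reads whose CDR3 was listed in a node library drawn to 7534295 reads. A set of 200 CDR3s with the smallest p among those higher after antigen than after adjuvant was carried to the mediastinal nodes as an immunization signature, beside a mirror set of 200 CDR3s higher after adjuvant. Shares of single libraries carry Wilson 95% confidence intervals.

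Whether sample numbers pair the libraries was checked before any calls were compared, from the correlation across CDR3s of each library's deviation from its group mean. Same-numbered heart and MI node libraries correlated at 0.197, 0.168 and 0.222 across CDR3s, so a fit with the number as a block stands beside the heart results it changed. Same-numbered MI and sham nodes correlated across CDR3s at -0.00384, -0.00371 and -0.0220, and heart extract and adjuvant nodes at 0.00317, 0.0155 and 0.0135, so their numbers were not taken to pair them.

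The methods were tested on data simulated from the lymph node libraries' counts and spread, with changes set between MI and sham nodes. At the real spread between libraries, 1.5-fold changes in TRBJ2-2 and in TRBV19 were recovered in 100% of simulated sets. Changes of 1.25-fold in TRBJ1-2 and in TRBV5 were recovered in 100% and 82%. Any TRBJ or TRBV call arose in 8% and 4% of sets without a change. No other segment was changed, so these rates do not cover rare or more variable segments. For single CDR3s, whose common dispersion was 9.94, neither 10-fold nor 1000-fold changes were recovered (0%), so a count of 0 CDR3s between MI and sham nodes carries little information about single CDR3s. The other contrasts were not simulated.

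Alternatives fixed before the data were examined were TMM factors, DESeq2 1.42.0 with poscounts size factors, the number as a block, fits of only the groups compared, other low-count filters, distinct CDR3s in place of reads, other depths and each library left out in turn. Alternatives chosen after seeing the data were leaving out entries with under 10 reads, edgeR without its legacy settings, DESeq2 on the mediastinal nodes alone, equal numbers of CDR3s per node library, and comparisons of sham with adjuvant nodes and of myosin with heart extract. Leaving out CDR3s with a single read was planned and not run, since the tables list none. Measures were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.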

Results

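T cell receptor beta repertoires of sorted CD4+ T cells were read from 19 libraries of BALB/c mice. In mice whose left anterior descending coronary artery had been ligated, T cells came from the mediastinal lymph nodes that drain the heart (n = 3) and from the infarcted heart itself (n = 3). Mediastinal nodes of sham-operated mice (n = 4), which had a thoracotomy without ligation, were the surgical control. Axillary nodes came from mice injected under the skin with Titermax adjuvant alone (n = 4), with porcine cardiac myosin (n = 2) or with mouse heart extract (n = 3). Node libraries held between 7534295 and 9235800 reads and heart libraries between 2426715 and 5126910 reads, each read carrying a CDR3, the loop that contacts the antigen peptide, with its TRBV and TRBJ segment. The libraries together listed 1082330 distinct CDR3 amino acid sequences. Of the 1074236 CDR3s seen in nodes, 77.1% were in 1 node library only and 316 were in all 16. How many of the node CDR3s were PCR or sequencing errors was not tested.

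The most abundant CDR3 of every node library held a small share of its reads. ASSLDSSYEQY with TRBV14 reached the highest such share, 0.399% of the reads of sham node 4 (95% Wilson interval 0.395% to 0.403%). In the hearts, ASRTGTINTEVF held 2.81% of the reads of heart 1 (interval 2.79% to 2.83%), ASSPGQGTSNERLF 3.30% of heart 2 (3.28% to 3.32%) and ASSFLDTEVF 3.35% of heart 3 (3.33% to 3.36%), all with TRBV14. The 100 most abundant CDR3s held 64.3% ± 6.19 of heart reads (SD, n = 3) and 2.49% ± 0.303 of MI node reads (n = 3). Hearts came from 5000 sorted cells and nodes from 500000, so this difference cannot be separated from cell number.

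**Figure D1:**
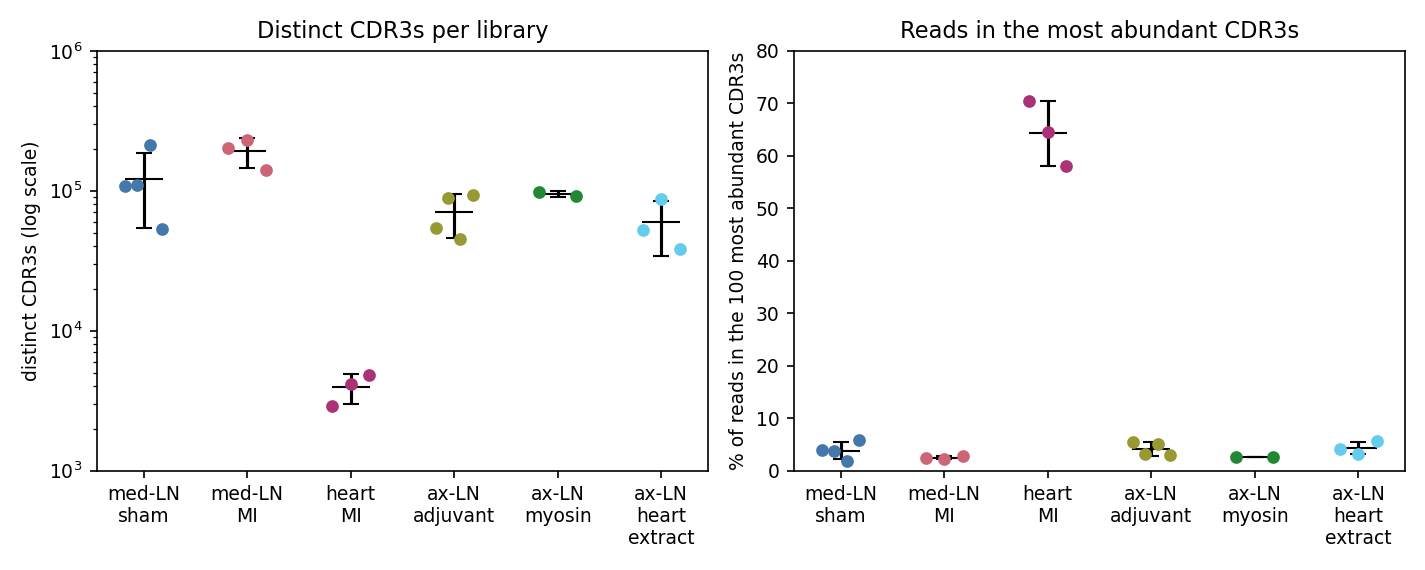
Distinct CDR3s per library on a log scale, and the percentage of reads in the 100 most abundant CDR3s, for the 6 groups. Points are libraries and bars the mean ± SD. Hearts, with 5000 sorted cells each, held 2898 to 4795 distinct CDR3s, and every node library, with 500000 sorted cells, at least 38437.

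The first comparison asked whether infarction changed the CD4+ repertoire of the heart-draining node. The segments of the MI nodes stood close to those of the sham nodes. TRBV19, which encodes Vβ6 and was the most used segment, held 23.7% ± 0.654 of reads after MI (n = 3) and 23.8% ± 1.03 after sham surgery (n = 4). TRBV14 held 13.2% ± 0.491 and 13.8% ± 0.559, TRBV1 8.87% ± 0.230 and 8.59% ± 0.418, TRBV13-1 3.21% ± 0.0140 and 3.31% ± 0.0665, and TRBV13-2 4.57% ± 0.0705 and 4.72% ± 0.211. These 4 segments had the smallest p among 22, and each had an adjusted p of 0.976. By edgeR, 0 TRBV segments passed after Benjamini-Hochberg adjustment, 0 had an unadjusted p under 0.05, and DESeq2 also called 0. Among TRBJ segments, TRBJ1-2 held 4.77% ± 0.216 after MI and 4.40% ± 0.292 after sham surgery, a log2 fold change of 0.12 (SE 0.0426, adjusted p 0.0675). TRBJ1-3 (0.09), TRBJ2-2 (-0.09) and TRBJ2-5 (-0.09) followed, with adjusted p of 0.135, 0.135 and 0.152. EdgeR called 0 of 11 TRBJ segments, 3 had an unadjusted p under 0.05, and DESeq2 called 0. TMM factors, and edgeR without its legacy settings, did give TRBJ calls, and leaving out entries with under 10 reads gave TRBV calls (counts given below). Without sham node 1, whose TRBJ1-2 share of 4.83% stood above the 4.22% to 4.28% of the other sham nodes, 8 TRBJ segments passed; 1 passed without sham node 4 and 1 without MI node 1.

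The CDR3s with the smallest p between MI and sham nodes, none of which passed, each had most of their reads in a single MI node. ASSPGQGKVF, with TRBV19 in the reads of MI node 3, held 0.240% of that library (interval 0.236% to 0.243%), had 28 reads in MI node 1 and was also listed with 16504 reads in heart 3. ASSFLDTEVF, the most abundant CDR3 of heart 3, had 7037 reads in MI node 3 and none in the other MI nodes. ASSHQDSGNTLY had 8719 reads in MI node 2 alone, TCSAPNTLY 3429 in MI node 3, 33 in MI node 2 and 30 in MI node 1, and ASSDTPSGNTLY 2828 in MI node 1 and 16 in MI node 2. None of the 5 was listed in a sham node, so that their mean shares were at least 2321-fold, 743-fold, 995-fold, 370-fold and 364-fold higher after MI in this order. They had the smallest p of 121771 CDR3s tested, and each had an adjusted p of 0.455. By edgeR 0 CDR3s passed and 11900 had an unadjusted p under 0.05. DESeq2 called 4566 in the fit of all nodes, and 1 when only the mediastinal nodes were fitted. In data simulated for MI against sham nodes with the spread of the node libraries, 0% of 1000-fold changes in a single CDR3 were recovered.

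The MI nodes held more distinct CDR3s on average, 190506 ± 45917 (n = 3) against 120122 ± 66305 (n = 4), and a smaller share in the 100 most abundant CDR3s, 2.48% ± 0.307 against 3.84% ± 1.64. Neither difference exceeded the spread between libraries (exact two-sided permutation p 0.171 and 0.229, adjusted p 0.229 for both, with 0.0286 the smallest p that 35 splits allow). The TRBJ1 cluster held 42.4% ± 0.801 of MI node reads and 39.7% ± 2.90 of sham node reads (exact permutation p 0.200, adjusted p 0.400), and the TRBV13 family, which encodes Vβ8, 9.23% ± 0.0484 and 9.49% ± 0.185 (p 0.0857, adjusted p 0.343). The 5 segments deleted by mammary tumor virus superantigens in this strain held 2.91% ± 0.482 and 3.03% ± 0.505 (exact permutation p 0.771, adjusted p 0.971). The CDR3 centre over distinct CDR3s carried a mean net charge of -0.0952 ± 0.00295 after MI and -0.0721 ± 0.0233 after sham surgery (exact permutation p 0.0857, adjusted p 0.429). Without sham node 4 the differences of MI from sham nodes were smaller for distinct CDR3s (47895.3), the 100 most abundant CDR3s (-0.716 percentage points), the TRBJ1 cluster (1.61 points) and this charge (-0.0115). Mean CDR3 length over reads was 12.1 residues in both groups, and a hydrophobic pair at positions 6 and 7 was in 0.869% ± 0.0845 and 0.926% ± 0.125 of reads (exact permutation p 0.714 and 0.686, adjusted p 0.857 for both).

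Immunization asked which receptors heart antigens raise in nodes that drain the injection site. TRBV19 rose from 21.9% ± 1.05 of reads after adjuvant alone (n = 4) to 24.4% ± 1.02 after heart extract (n = 3), a log2 fold change of 0.16 (SE 0.0441, edgeR adjusted p 0.0337). TRBV5, which encodes Vβ1, fell from 21.5% ± 0.226 to 19.2% ± 1.18, a log2 fold change of -0.16 (SE 0.0390, adjusted p 0.0232). After myosin, TRBV19 held 23.8% ± 0.962 and TRBV5 20.04% ± 0.102 (n = 2), which did not pass against adjuvant (log2 0.12 and -0.10, adjusted p 0.477 for both). With both antigens together against adjuvant, TRBV19 rose by 0.14 (SE 0.0389) and TRBV5 fell by 0.14 (SE 0.0341), each with an adjusted p of 0.0298. These 2 segments were the only TRBV calls, and the adjuvant volume, which the labels give as higher for some immunized animals, is not separable from the antigen. Sham mediastinal nodes, from another site and not immunized, held 22.3% to 24.8% of reads with TRBV19 and 19.0% to 20.4% with TRBV5. They differed from the adjuvant nodes in the same directions (given below), so these shifts were not particular to antigen. With TMM factors, DESeq2 or distinct CDR3s in place of reads neither segment passed for either contrast, and DESeq2 called 0 TRBV segments for antigens against adjuvant.

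Leaving out a single library also ended calls of the antigen contrast. Without adjuvant node 1 the adjusted p was 0.129 for TRBV19 and 0.0968 for TRBV5, without adjuvant node 3 it was 0.127 and 0.0637, and without adjuvant node 4 it was 0.0780 for both. Over all libraries left out in turn, the log2 fold change stayed between 0.12 and 0.17 for TRBV19 and between -0.15 and -0.10 for TRBV5. TRBV5 alone passed without myosin node 1, heart extract node 2 or heart extract node 3. For heart extract against adjuvant, neither segment passed without adjuvant node 1, adjuvant node 4 or heart extract node 3, with adjusted p of 0.0667, 0.0735 and 0.116 for TRBV5, and the log2 fold changes stayed between 0.13 and 0.19 for TRBV19 and between -0.19 and -0.11 for TRBV5. TRBV5 alone passed without adjuvant node 3 or heart extract node 2. The exact permutation test of the TRBV19 share, planned as a segment list, gave p 0.0397 (two-sided, 126 splits) and an adjusted p of 0.159.

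**Figure D2:**
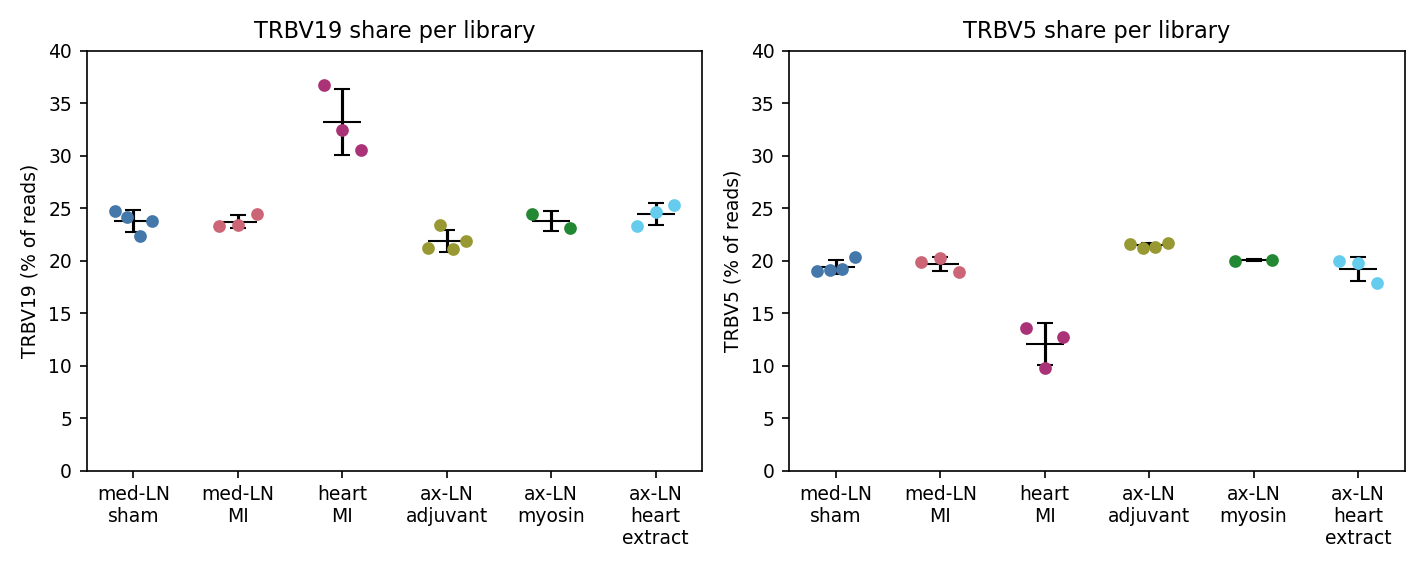
Percentage of reads with TRBV19 and with TRBV5 in each library, by group. Points are libraries and bars the mean ± SD; TRBV19 lay between 30.5% and 36.7% in the 3 hearts and between 21.1% and 25.3% in the node libraries.

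By edgeR no TRBJ segment or CDR3 passed between antigen and adjuvant nodes, whereas DESeq2 called CDR3s in every contrast. TRBJ2-5 held 9.71% of reads after myosin, 9.70% after heart extract and 9.18% after adjuvant, with a log2 fold change of 0.08 for both antigens together (adjusted p 0.634). TRBJ1-5 (0.11), TRBJ1-1 (-0.09) and TRBJ2-2 (0.03) followed with adjusted p of 0.667, 0.667 and 0.859. For myosin the next smallest p after TRBJ1-2 (0.09) belonged to TRBJ2-5, TRBJ1-5 and TRBJ1-1, with adjusted p from 0.551 to 0.985, and for heart extract to TRBJ2-4, TRBJ1-1 and TRBJ1-5 after TRBJ2-5, with adjusted p from 0.578 to 0.791. By edgeR 0 TRBJ segments passed in the 3 contrasts, 0 had an unadjusted p under 0.05, and DESeq2 called 0. TRBV13-2 and TRBV20 completed the 4 segments with the smallest p for myosin, at an adjusted p of 0.974.

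The CDR3s with the smallest p for both antigens together were CDR3s of adjuvant nodes. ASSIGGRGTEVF was in all 4 adjuvant nodes, with 3969, 268, 747 and 461 reads, and in none of the 5 antigen nodes, at least 465-fold lower. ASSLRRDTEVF had 6169 reads in adjuvant node 3, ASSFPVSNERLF 5074 in adjuvant node 1, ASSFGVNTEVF 4120 in adjuvant node 3, and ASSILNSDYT 4577 in adjuvant node 1 and 464 in adjuvant node 2. Each of these 5 had an adjusted p of 0.209. Against adjuvant, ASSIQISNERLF was in both myosin nodes (733 and 1264 reads) and in all 3 heart extract nodes (682, 374 and 536 reads) without a listed read in an adjuvant node, at least 348-fold higher after myosin. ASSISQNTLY was in both myosin nodes with 887 and 465 reads, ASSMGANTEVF in both with 1069 and 166, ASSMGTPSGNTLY in myosin node 1 with 2911 and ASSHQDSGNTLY, also abundant in MI node 2, in myosin node 1 with 1136. These had an adjusted p of 0.369. For heart extract, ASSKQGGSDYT had 10980 reads in heart extract node 3 and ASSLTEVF 4450 in heart extract node 1 and 171 in heart extract node 2, but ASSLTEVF was also in all 4 sham nodes, with 7820 reads in sham node 2. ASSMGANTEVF had 748 and 3321 reads in heart extract nodes 2 and 3, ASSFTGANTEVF 5, 64 and 4251 in heart extract nodes 1, 2 and 3, and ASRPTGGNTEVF 4803 in heart extract node 1. Their adjusted p was 0.258. EdgeR called 0 CDR3s for both antigens, myosin or heart extract, with 26570, 16360 and 18224 at an unadjusted p under 0.05, and DESeq2 called 15621, 11992 and 14333.

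The antigen nodes held 73454 ± 26210 distinct CDR3s (n = 5) and the adjuvant nodes 70093 ± 24097 (n = 4, exact permutation p 0.833, adjusted p 0.833). The mean net charge of the CDR3 centre over reads was -0.0352 ± 0.0147 after antigen and -0.0545 ± 0.0118 after adjuvant (exact permutation p 0.0794, adjusted p 0.476). The TRBJ1 cluster held 44.8% ± 1.64 and 45.7% ± 1.95 of reads, the TRBV13 family 9.58% ± 0.358 and 9.57% ± 0.371, and the superantigen-deleted segments 1.95% ± 0.210 and 1.84% ± 0.205 (exact permutation adjusted p 0.667, 0.968 and 0.667).

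Overlap between node repertoires was not higher within treatments than between them by more than chance gives. The mean Morisita-Horn overlap was 0.332 among MI nodes, 0.163 among sham nodes and 0.237 between MI and sham nodes, so that pairs within either group averaged 0.219 (exact one-sided permutation p 0.743, 35 splits). Sham node 3, with 212131 distinct CDR3s, overlapped MI nodes 1, 2 and 3 at 0.391, 0.433 and 0.317. Sham node 4, with 52869, overlapped them at 0.130, 0.138 and 0.119. How far the number of distinct CDR3s set these means was not tested. Without sham node 3 overlap within exceeded that between by 0.0405 (p 0.100, the smallest that 20 splits allow). It was 0.144 within and 0.145 between antigen and adjuvant nodes (p 0.373, 126 splits). The 200 CDR3s that ranked highest after antigen over adjuvant, of which 0 passed the test, held 0.314% ± 0.0436 of MI node reads and 0.314% ± 0.0679 of sham node reads (exact permutation p 1.00). The mirror set of 200 CDR3s higher after adjuvant held 0.177% ± 0.0217 and 0.224% ± 0.0878 (exact permutation p 0.543). No TRBJ or TRBV segment differed between the MI effect and the antigen effect when the difference itself was tested by edgeR.

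The infarcted heart was compared with the MI node to ask which receptors entered the injured tissue. TRBV19 rose from 23.7% ± 0.654 of node reads to 33.2% ± 3.17 of heart reads (n = 3 each), a log2 fold change of 0.49 (SE 0.125, edgeR adjusted p 9.2e-04), and as a planned segment list it had an exact permutation p of 0.100 and an adjusted p of 0.400. TRBV5 fell from 19.7% ± 0.681 to 12.05% ± 1.997 (log2 -0.71, adjusted p 2.5e-05), and TRBV4, which encodes Vβ10, from 8.12% ± 0.633 to 5.86% ± 0.762 (log2 -0.47, adjusted p 0.00201). TRBV26, which encodes the superantigen-deleted Vβ3, fell from 0.117% ± 0.0691 to 4.05e-04% ± 3.71e-04, with 57 heart reads in all (adjusted p 5.2e-04). TRBV23 and TRBV24 had 0 listed heart reads, at least 67.4-fold and 407-fold lower than in the nodes (adjusted p 5.5e-08 and 5.8e-07). At their node shares, 5000 sorted heart cells would hold 0.281 cells with TRBV23, 1.70 with TRBV24 and 5.87 with TRBV26, if reads followed cells. The absence of TRBV23 and TRBV24 reads could therefore arise without a change in their share of cells. TRBJ2-1 rose from 9.84% ± 0.0416 to 15.1% ± 3.42 (log2 0.62, SE 0.185, adjusted p 0.0278), the only TRBJ call.

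In a comparison chosen after the data were seen, the 100 most abundant CDR3s of each library were left out, which held 64.3% of heart reads and only 2.49% of MI node reads. In the rest TRBV19 held 8.60% ± 2.46 of heart reads and 23.6% ± 0.553 of node reads, and TRBV5 15.95% ± 1.54 and 19.8% ± 0.543 (n = 3 each, exact permutation p 0.100 for both). With the sample number as a block in edgeR, the adjusted p was 0.0557 for TRBV19, 0.00130 for TRBV5, 0.00126 for TRBV4 and 0.154 for TRBJ2-1. TMM factors left TRBV5 and TRBV4 without a call (adjusted p 0.0623 and 0.477), as did DESeq2 (0.0891 and 0.603), and counting distinct CDR3s turned their log2 fold changes to 0.07 and 0.03. In the hearts most distinct CDR3s had under 100 reads, so that count rests mainly on them. Without the legacy settings of edgeR, chosen after the data were seen, TRBV19 was the only TRBV call (adjusted p 8.9e-04), with TRBV5 at 0.120 and TRBV4, TRBV23, TRBV24 and TRBV26 at 0.978. Leaving out segments under 0.1% left 3 TRBV calls, TRBV19, TRBV5 and TRBV4. TRBV4 did not pass without MI node 2 (adjusted p 0.0700), nor TRBJ2-1 without MI node 1 (0.164), MI node 2 (0.125), MI node 3 (0.201) or heart 2 (0.126), while with each library left out in turn their log2 fold changes ran from -0.58 to -0.39 and from 0.45 to 0.78.

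Of 24255 CDR3s tested between heart and MI node, edgeR called 58 higher and 23260 lower in the heart. The low-count filter largely set the lower count: a CDR3 without a heart read was tested only if it was in all 3 MI nodes, and all 22912 of these were called lower. Of the 1343 tested CDR3s with a heart read, 58 were higher and 348 lower. The lower ones named by rule, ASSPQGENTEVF, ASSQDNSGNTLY, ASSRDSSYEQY, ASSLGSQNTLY and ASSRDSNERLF, were in all 3 MI nodes and had no listed heart read, at least 460-fold, 364-fold, 320-fold, 315-fold and 297-fold lower (adjusted p 0.0214, 0.00911, 0.00699, 0.00707 and 0.00632). At their node shares 0 of the 23260 CDR3s would have reached 3 of the 5000 heart cells, with a median of 0.0355 cells, but together they would have held 1472 cells. Of the 23999 CDR3s found in all 3 MI nodes, 1400 would be expected in 5000 cells drawn at node shares, if reads followed cells and every sorted cell was captured. Hearts 1, 2 and 3 listed 154, 278 and 324. In these hearts only 313, 439 and 550 CDR3s of any kind had at least 1000 reads. Whether the shortfall was particular to CDR3s of all 3 MI nodes was not tested, since no expectation was computed for the others. By reads the shortfall was smaller, since the CDR3s found in all 3 MI nodes held 20.9%, 24.6% and 27.9% of the reads of hearts 1, 2 and 3. They held 29.1%, 28.6% and 33.9% of the reads of MI nodes 1, 2 and 3. The 10 higher ones named by rule each had reads in a single heart, from 246 for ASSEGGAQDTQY in heart 1 to 2879 for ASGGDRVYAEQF in heart 3, and 2 to 11 reads in each of 2 MI nodes. The others were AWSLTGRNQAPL, GASTGGNERLF and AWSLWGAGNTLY in heart 2, and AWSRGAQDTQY, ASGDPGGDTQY, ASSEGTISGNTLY, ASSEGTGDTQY and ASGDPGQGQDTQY in heart 3. The call rested on the setting: with the sample number as a block 0 CDR3s passed, without a low-count filter 356 were higher and 2 lower, and DESeq2 called 4 higher and 22976 lower. Without any 1 of the MI nodes 0 passed, but the filter of 3 libraries then left out every CDR3 without a heart read. That loss was therefore largely set by the filter. In the blocked fit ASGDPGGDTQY, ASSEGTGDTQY and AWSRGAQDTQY turned to log2 fold changes of -2.53, -2.29 and -1.001, and with TMM factors 0 CDR3s were higher.

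Heart libraries held 3722 ± 755 distinct CDR3s and MI nodes 173263 ± 42249 at an equal 2426715 reads, and their normalised Shannon entropy was 0.678 ± 0.0113 against 0.933 ± 0.00289 (exact permutation p 0.100 for both, the smallest that 20 splits allow). Reads were equalised but cells were not, 5000 sorted per heart and 500000 per node library, so these differences cannot be separated from cell number. Per 100 sorted cells, with all reads, hearts 1, 2 and 3 listed 58.0, 83.1 and 95.9 distinct CDR3s. MI nodes 1, 2 and 3 listed 40.2, 46.1 and 28.2. Depth per sorted cell was unequal, with 485, 880 and 1025 reads in hearts 1, 2 and 3. In MI nodes 1, 2 and 3 it was 15.1, 16.9 and 18.3 reads, so these counts do not compare diversity per cell. Most of the distinct heart CDR3s had few reads: in heart 1, 2 and 3, 2494, 3569 and 4084 CDR3s had under 100 reads and held under 1% of the reads, and 313, 439 and 550 had at least 1000. A hydrophobic pair at positions 6 and 7 was in 0.447% ± 0.191 of heart reads and 0.868% ± 0.0838 of node reads (exact permutation p 0.100, adjusted p 0.300). The superantigen-deleted segments held 3.31% ± 0.196 of heart reads and 2.91% ± 0.481 of node reads, the TRBV13 family 9.67% ± 1.45 and 9.23% ± 0.0731, and the TRBJ1 cluster 41.7% ± 4.24 and 42.4% ± 0.812 (exact permutation adjusted p 0.600, 0.900 and 0.900).

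The last question was whether receptors of the infarcted heart are found in its draining node. Each heart's most abundant CDR3 was in the node of its own number. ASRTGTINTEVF of heart 1 had 242 reads in MI node 1 and none in another node library, and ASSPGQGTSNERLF of heart 2 had 1086 reads in MI node 2 and none elsewhere. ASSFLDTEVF of heart 3 had 7037 reads in MI node 3 and 2 reads each in adjuvant node 2 and myosin node 2. Of each heart's 100 most abundant CDR3s, 57, 58 and 49 were in the same-numbered MI node, and 76, 84 and 78 in any of the 16 node libraries. In the other-numbered MI nodes the counts were 44 and 33 for heart 1, 42 and 42 for heart 2, and 42 and 45 for heart 3. MI nodes held the CDR3s of 43.1% ± 5.77 of heart reads (n = 3) and sham nodes those of 28.1% ± 10.5 (n = 4), a difference within the spread between nodes (exact permutation p 0.0857). With equal numbers of CDR3s per node, chosen after the data were seen, these were 29.6% and 21.9% (p 0.114). Same-numbered nodes held 52.4% and other-numbered MI nodes 38.4%, the highest of the 6 possible pairings (one-sided exact permutation p 0.167, the smallest they allow). With equal numbers of CDR3s per node these were 38.0% and 25.4%. Counted as distinct CDR3s, same-numbered nodes held 15.1% and other-numbered MI nodes 12.3%, but heart 3 had 14.7% in MI node 2 and 14.4% in MI node 3. The other-numbered MI nodes exceeded the sham nodes by 10.3 percentage points (p 0.171), and by 3.50 with equal numbers of CDR3s per node (p 0.429). No CDR3 was in all 3 hearts, and 38 of 11808 were in at least 2. Counts of distinct heart CDR3s rest mainly on CDR3s with under 100 reads, 4084 of 4795 in heart 3. Of these 89.2% lay 1 amino acid from a CDR3 with at least 1000 reads in that heart.

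**Figure D3:**
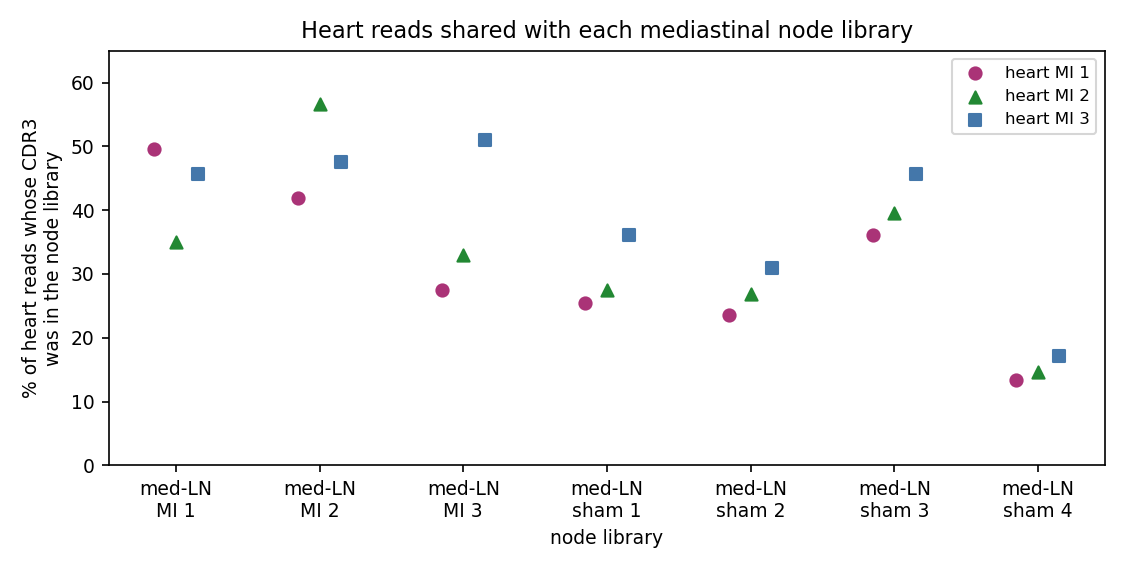
Percentage of each heart library's reads whose CDR3 was listed in each mediastinal node library, at equal node depth. Each heart had its highest value in the MI node of its own number, 49.6%, 56.6% and 51.0%; values in sham nodes ran from 13.4% to 45.8%.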

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

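The tests of carry-over from heart to node, node richness and same-numbered pairs were chosen after the results they measure were seen, and the tests of the other patterns after the patterns themselves. Of 89 groups of 4 libraries, 11 held a library far from the others, and chance gives about 1 in 20, a rate that does not apply to 5 of the 11, CDR3s named for their small p between antigen and adjuvant nodes. TRBJ1-1 held 18.1% of reads in adjuvant node 1 against 15.5% to 15.8% in the other adjuvant nodes, and TRBV23 held 0.00786% in adjuvant node 4 against 0.00241% to 0.00321%. TRBJ1-2 held 4.83% in sham node 1 against 4.22% to 4.28% in the other sham nodes, and TRBV5 20.4% in sham node 4 against 19.0% to 19.2%. In sham node 4 the hydrophobic pair was in 1.11% of reads against 0.852% to 0.880%, and the charge over distinct CDR3s was -0.0374 against -0.0875 to -0.0812. Adjuvant node 3 held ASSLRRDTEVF at 0.0755% and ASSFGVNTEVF at 0.0505%, and adjuvant node 1 held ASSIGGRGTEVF at 0.0515%, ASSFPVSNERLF at 0.0658% and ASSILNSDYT at 0.0593%, each far above the other adjuvant nodes.

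The CDR3s of heart reads were found most often in the MI node of the same number, although of the distinct CDR3s of heart 3, 14.7% were in MI node 2 and 14.4% in MI node 3. Of these 4795 distinct CDR3s, 4084 had under 100 reads. Carry-over of heart reads in proportion to their number would have reached the same-numbered node for every abundant heart CDR3. Its rate was taken as the node reads per heart read over all heart CDR3s, 0.0269, 0.0176 and 0.0297 in hearts 1, 2 and 3. Of 1354 CDR3s predicted to have at least 20 node reads, 685 had none, at least 46.7% in each heart, which argues against carry-over at that rate. The rate also counts reads of CDR3s that the node may have held on its own, so carry-over at a lower rate was not tested. Node richness would favour MI node 2, the richest with 230684 distinct CDR3s, for every heart. Of the heart CDR3s with at least 1000 reads found in exactly 1 MI node, however, 54 of 82, 76 of 115 and 64 of 114 were in the same-numbered node. These were 65.9%, 66.1% and 56.1%, where node richness gives 35.1%, 41.9% and 24.6%, at least 24.2 percentage points less, which argues against richness as the whole cause. The one-sided binomial p (1.4e-08, 1.4e-07 and 6.9e-13) treats the CDR3s of a pair of libraries as independent. With 3 pairs it measures no spread between libraries. That same-numbered libraries came from the same animal, with T cells of a clone in both tissues, is a candidate explanation that stays open, because the 6 pairings cannot give a p under 0.167.

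TRBV19 was higher and TRBV5 lower in the hearts than in the MI nodes. A few expanded CDR3s may set these shares, but this stays open: without the 100 most abundant CDR3s of each library the log2 ratio of heart to node was -1.46 for TRBV19 and -0.31 for TRBV5, and the 100 held 64.3% of heart reads against 2.49% of node reads, so unlike parts were compared. TRBV19 made up 13.8% of the heart CDR3s with at least 1000 reads, each counted once, and 33.2% of heart reads. Of the CDR3s with at least 10 reads it made up 25.98%, 21.46% and 23.25% in hearts 1, 2 and 3. In MI nodes 1, 2 and 3 it made up 15.8%, 15.8% and 12.7% of such CDR3s, and 23.7% of reads on average. The cut of 10 reads also takes in heart CDR3s with under 100 reads, whose main source may be errors (below). CDR3s with at least 1000 reads held 97.4%, 97.9% and 97.8% of the reads of hearts 1, 2 and 3. TRBV19 made up 15.3%, 13.2% and 12.7% of them, close to its shares of MI node CDR3s. Within the hearts its share of reads thus came from more reads for each abundant TRBV19 CDR3. This argues against more abundant TRBV19 CDR3s as the source, although node CDR3s were counted at the lower cut of 10 reads. Amplification could favour TRBV19, whose median reads per CDR3 were at least 2.23 times those of other segments in every node library, but 0.780, 1.08 and 0.729 times in hearts 1, 2 and 3, where CDR3s with at least 1000 reads had medians of 13202, 17546 and 18254.5 with TRBV19 and 3325, 3842 and 3942 with other segments. A factor common to all libraries would cancel between heart and node, and a larger expansion of TRBV19 clones in the heart was not tested apart from this.

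Each heart library listed many CDR3s with low read counts, 2494, 3569 and 4084 with under 100 reads. PCR or sequencing errors may be their main source, since 89.8% of heart CDR3s under 100 reads lay 1 amino acid from a CDR3 with at least 1000 reads in the same library. Of the same CDR3s 1.72%, 1.26% and 0.967% lay as close to an abundant CDR3 of another heart. Carry-over from the node libraries would need them to be in nodes, where 25.2% were, which argues against it as the main source.

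Chance could not be excluded for the TRBV calls of immunized nodes. For both antigens against adjuvant, 7 of 100 splits gave at least the real 2 TRBV calls, with up to 3 in another split, and for heart extract against adjuvant 4 of 35 splits gave at least 2, with 2 the highest of the others. Where the real groups gave 0 calls every split gives at least as many, so that the count says nothing about chance. This held for 35 of 35 splits of MI and sham nodes, with up to 8 TRBJ, 5 TRBV and 0 CDR3 calls in another split and a median of 0 for each, and whether the 8 and 5 calls mark a structure of these libraries was not tested. It held for 100 of 100 splits of antigen and adjuvant nodes and 35 of 35 of heart extract and adjuvant nodes, with up to 1 TRBJ and 0 CDR3 calls in each. Heart and MI node allow 10 splits, too few for a share under 0.05, and the real groups, 1 of the 10, gave 1 TRBJ, 6 TRBV and 23318 CDR3 calls against 0 in every other split. These fits had no block for the sample number, and with that block the real groups gave 0 TRBJ and 0 CDR3 calls.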

How the results depend on the processing

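Tests chosen after seeing the data were those that left out entries with under 10 reads, edgeR without its legacy settings, DESeq2 on the mediastinal nodes alone and equal numbers of CDR3s per node. The planned test without single-read CDR3s was not run, because the tables list none, and a CDR3 left without reads in both groups gave no value. Where no cause is stated below, the cause was not tested. Cell number limits what a single CDR3 can show in the hearts, since at node shares 0 of the 23260 CDR3s called lower there would have reached 3 of 5000 cells, although together they would have held 1472 cells. For single CDR3s between MI and sham nodes the spread between libraries was the limit. Depth was varied for the measures alone: drawing to a lower depth, tried for the diversity measures only, and using all reads changed no direction or call.

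TRBV calls for both antigens and for heart extract against adjuvant numbered 2 each, and fell to 0 with TMM factors, with DESeq2 and with distinct CDR3s in place of reads. With heart extract and adjuvant alone in the fit, 0 passed for that pair. DESeq2 called 4566 CDR3s for MI against sham nodes, 15621 for both antigens, 11992 for myosin and 14333 for heart extract, where edgeR called 0. Fitted to the mediastinal nodes alone, DESeq2 called 1. TRBJ calls for MI against sham nodes, 0 in edgeR, were 1 with TMM factors and 2 without legacy settings, and TRBV calls were 2 without entries under 10 reads. Without legacy settings heart against MI node gave 2 TRBJ and 1 TRBV calls. Leaving out segments under 0.1% gave 3 TRBV calls there, and distinct CDR3s gave 10 TRBV and 0 TRBJ calls. CDR3 calls there, 23318, were 14645 without entries under 10 reads, 358 without a low-count filter and 0 with the stricter filter, which left 18 CDR3s to test.

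With the sample number as a replicate block, heart against MI node gave 0 CDR3 and 0 TRBJ calls, and the log2 fold changes of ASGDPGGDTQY, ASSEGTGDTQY and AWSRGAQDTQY turned to -2.53, -2.29 and -1.001. The block left 1 TRBV call each for both antigens and for heart extract. In same-numbered MI and sham pairs the hydrophobic pair differed by 0.00585 percentage points over reads and 0.00271 over distinct CDR3s, against the negative differences of the unpaired groups.

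Directions that turned with distinct CDR3s were those of TRBV5 (0.0738) and TRBV4 (0.0252) between heart and MI node, TRBV13-1 (0.0610), TRBV13-2 (0.0767) and TRBJ2-2 (0.000365) between MI and sham nodes, and TRBJ2-2 (-0.00485) between antigen and adjuvant nodes. In the hearts such counts rest mainly on CDR3s with under 100 reads. Over distinct entries the TRBV13 family differed by 1.60 points between MI and sham nodes and by -6.53 between heart and MI node, and the TRBJ1 cluster by 0.156 there. Without entries under 10 reads, differences that turned were 0.0138 for the charge over distinct CDR3s and 0.704 points for TRBV19 between MI and sham nodes, -0.0868 points for the TRBV13 family between antigen and adjuvant nodes, and -0.00480 for the charge over reads between heart and MI node. The antigen signature differed between MI and sham nodes by -0.0569 points with 1000 CDR3s, -3.87e-04 with CDR3s of at least 3 antigen and no adjuvant libraries, and -0.00622 as a share of distinct CDR3s. Apart from TRBV5 and TRBV4 between heart and MI node, none of these had passed its test.

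Leaving out 1 library at a time gave 0 to 8 TRBJ calls for MI against sham nodes, 0 to 2 TRBV calls for both antigens and for heart extract, and 0 to 3 TRBJ and 0 to 23493 CDR3 calls for heart against MI node. Without an MI node, where that CDR3 count was 0, no CDR3 without a heart read could enter the test. Between MI and sham nodes the differences ran from -0.0109 to 0.00659 residues for length over reads, from -0.00133 to 0.0271 over distinct CDR3s, from -0.101 to 0.00585 points for the hydrophobic pair over reads and from -0.0355 to 0.0487 over distinct CDR3s. They ran from -0.284 to 0.152 points for the superantigen-deleted segments, from -0.492 to 0.317 for TRBV19, from -0.0249 to 0.0303 for the antigen signature and from -0.0554 to 0.0405 for overlap within minus between groups. Between antigen and adjuvant nodes they ran from -0.00993 to 0.00695 for length over reads, from -0.00516 to 0.0357 for the hydrophobic pair over distinct CDR3s, from -1.42 to 0.104 for the TRBJ1 cluster and from -0.108 to 0.160 for the TRBV13 family. The ranges were -4951.6 to 12119.5 for distinct CDR3s, -0.00245 to 0.0114 for entropy and -0.00678 to 0.00717 for overlap. Between heart and MI node they ran from -0.106 to 0.0732 for length over reads, from -0.110 to 0.0146 over distinct CDR3s, from -0.0398 to 0.0279 for charge over reads, from -0.222 to 0.00309 for the hydrophobic pair over distinct CDR3s, from -2.33 to 1.74 for the TRBJ1 cluster and from -0.267 to 1.18 for the TRBV13 family.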

Other observations

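The comparisons of sham mediastinal with adjuvant axillary nodes and of myosin with heart extract, the splits of the sham and adjuvant libraries and the set of CDR3s found in every sham node, were chosen after the data were seen. Sham mediastinal nodes and adjuvant axillary nodes, the controls of the 2 experiments, differed in node site and in treatment alike. TRBV16, which encodes the superantigen-deleted Vβ11, held 1.79% ± 0.253 of reads in the sham nodes and 0.882% ± 0.131 in the adjuvant nodes (SD, n = 4 each), a log2 fold change of 1.02 by edgeR (adjusted p 1.0e-04). TRBV4 held 7.85% ± 0.114 and 9.98% ± 0.536 (log2 -0.35, adjusted p 7.4e-05), and TRBV2 4.19% ± 0.184 and 4.92% ± 0.264 (log2 -0.23, adjusted p 8.5e-04). TRBV19 was higher in the sham nodes (log2 0.12, adjusted p 0.0315) and TRBV5 lower (log2 -0.14, adjusted p 0.00748). The other calls were TRBV12-1 (1.22), TRBV29 (1.19) and TRBV1 (0.12) higher, and TRBV17 (-0.31) and TRBV20 (-0.13) lower, 10 of 22 segments in all, and DESeq2 also called 10. Only 1 of the 35 splits of these 8 libraries, the real one, gave as many, with at most 1 call in another split. That is the smallest share that 35 splits allow, in a comparison chosen after the data were seen. It therefore counts against chance without excluding it.

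Of the 6 TRBJ2 segments, 4 were higher in the sham nodes than in the adjuvant nodes. TRBJ2-4 held 9.31% ± 0.551 and 7.84% ± 0.281 (log2 0.25, edgeR adjusted p 1.8e-08), TRBJ2-2 5.97% ± 0.0837 and 5.04% ± 0.102 (log2 0.24, adjusted p 2.8e-09), and TRBJ2-5 (0.18) and TRBJ2-1 (0.17) were also higher, whereas TRBJ2-3 (0.05, adjusted p 0.353) and TRBJ2-7 (0.10, adjusted p 0.110) did not pass. TRBJ1-1 held 13.3% ± 1.32 and 16.2% ± 1.23 (log2 -0.28, adjusted p 5.1e-04), and TRBJ1-2 (-0.14), TRBJ1-3 (-0.14) and TRBJ1-4 (-0.19) were also lower. For these 8 calls chance could not be excluded, since 3 of 35 splits of the 8 libraries gave at least as many, with up to 10 in another split. Between myosin and heart extract nodes, edgeR called 0 TRBV and 0 TRBJ segments, with 0 and 1 at an unadjusted p under 0.05, and DESeq2 called 0 of either.

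A set of 4146 CDR3s was found in all 4 sham nodes. These CDR3s held 9.45% ± 0.164 of MI node reads (n = 3), 9.504% ± 0.387 of adjuvant node reads (n = 4), 9.60% ± 0.0591 of myosin node reads (n = 2) and 9.37% ± 0.0982 of heart extract node reads (n = 3). The sham nodes, on which the set was chosen, held 12.5% ± 4.28, with 18.9% in sham node 4. Hearts 1, 2 and 3 listed 50, 75 and 105 of the CDR3s, and these held 7.83% ± 1.57 of heart reads (n = 3), which did not differ from the MI nodes beyond the spread (exact two-sided permutation p 0.300).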
